A study of Drosophila melanogaster with 2 samples.

How the data were processed

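Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out, per the labels, on whole Drosophila melanogaster embryos collected from 0 to 24 h that carried an eGFP fusion of CG7372, with an antibody against GFP. Chromatin was sheared by sonication to fragments of 200 to 800 bp, per the labels. The labels give 2 biological replicates of 1 group, numbered 1 and 2. No control library was analysed here.

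The files analysed were 8 peak lists on the dm6 assembly. Each replicate has a ranked and a thresholded list from IDR, the irreproducible discovery rate. The whole series has a ranked and a thresholded conservative list and a second ranked and thresholded pair, called the series-level lists here. Per the file headers, the lists of the whole series were made from the alignments of both replicates with further inputs that are not named, so their peaks are not calls on single samples. The aligner, the peak caller, their versions and settings are not given in the sources used here. The signal of each peak is the authors' own value, on a scale that is not stated, and it was used only to rank, describe or split peaks within 1 list. The score of each peak, as deposited, follows the IDR, and every thresholded list held only scores of 830 or more, the score at an IDR of 0.01. The deposited files also give the −log10 of a q-value for each peak and, in the ranked lists, the −log10 of the IDR. The −log10 q-values were not used. A further 16 columns in the ranked lists of the series, which hold values of the inputs that were compared, were not used. Sequencing depth is unknown, because the files give no read counts.

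The main peak set was the conservative thresholded list, taken on the arms 2L, 2R, 3L, 3R, 4, X and Y, which left out 1 of 4594 peaks. Peak ends and gene ends on every arm lay within the arm lengths of the reference used, the Release 6 sequence with the BDGP6.54 annotation of Ensembl release 115. This annotation held 18277 genes, 13968 of them protein-coding, and 24111 distinct transcription start sites (TSS) on these arms. The gene CG7372 is named Phs there, and 4 list members were matched through renamed symbols.

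Each summit was given 1 class, in the order promoter (within 500 bp of a TSS), 5′ UTR, CDS, 3′ UTR, intron, noncoding exon and intergenic. Shares were compared with 1000 random placements on the same arm by a two-sided permutation test, and p-values were adjusted by the Benjamini-Hochberg method within each family. The smallest p these permutations can give is 0.001. Overlap between replicates needed 1 shared bp and was compared with 1000 random placements. The correlation between replicates was taken across peaks, which are not independent replicates, with 100000 permutations. The strongest and weakest 25% of the peaks were compared by Fisher's exact test and arms by an exact binomial test against their non-N length. A gene was called bound if a summit lay within 500 bp of any of its TSS. For 28 gene lists, members were compared with all other protein-coding genes, or with all genes for the RNA classes, by Fisher's exact test. Divergent genes were those with a divergently oriented protein-coding TSS within 1000 bp. Odds ratios carry 0.5 added to each cell, so an odds ratio can pass 1 where the shares hardly differ. Sequence was read from 50 bp below to 50 bp above the summit and in 2 windows of the same length centred 300 bp to either side. All 8-bp words were tested on 2L, 3L and 4 by a one-sided Fisher's exact test, and the called words were tested again on 2R, 3R and X. A further 10 known sequences were tested two-sided on all arms. Intervals are 95% Wilson intervals unless stated, and they cover counting error only.

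These tests, the gene lists, the known sequences, most alternative settings and the rule for named genes were set before the data were examined. By that rule the text names CG7372, the gene with the TSS nearest to each of the 25 peaks of highest signal, up to 4 bound members of each list in order of signal, and every member of the Hox, pair-rule and insulator lists. Genes whose TSS lie within 500 bp of the same summit are not told apart, and such neighbours are not named for every gene. Members of multicopy families (histone, tRNA and snRNA genes) are uncertain, since reads may match several copies.

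The alternatives left out each replicate, used the series-level list, the part of the peaks above the median signal or merged peaks, and changed the TSS distance, the gene assignment, the word length, the flank distance or the overlap rule. A further 6 alternatives were chosen after seeing the data: unreproducible peaks as background, genes with a ranked peak as background, genes of the same promoter arrangement, a weight matrix in place of words, and windows without a called or without a leading word. The analysis was run several times, and the tests on word positions, base composition, peaks left out of the list and overlapping pairs were added after earlier results had been seen.

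The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The methods were tested on simulated data. Among 4000 simulated peaks, a part was planted at TSS and the rest placed at random. Together 35.2% were expected at promoters, and 35.2% were found there. In simulated draws of the 13968 protein-coding genes, 2% of runs called a list with no effect, and a list planted at 50% was called in 100.0% of runs. The test of divergent genes gave a p under 0.05 in 7% of 100 simulated runs with no effect. Both simulations drew each gene on its own, while in the data a summit can mark neighbouring genes together. They do not show how these tests behave under that dependence. A word planted in 4.65% of 4000 simulated windows ranked first, and no word was called without one. These windows were placed at random, while summits in the data were richer in A and T than their flanks. The simulation does not show how the word test behaves under that difference. The weight matrix did not recover the planted word at 4.65% and recovered it only after the planted share was raised to 24.3%, so it can miss a sequence present at few sites. For overlap, 50.1% of 2000 simulated peaks were found shared where 50% had been planted.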

Results

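CG7372, annotated as Phs, was profiled by ChIP-seq in 0 to 24 h whole embryos through an eGFP tag, in 2 biological replicates of 1 group. The design holds no second condition, so the data describe where the tagged protein was found, and no test between groups was possible. The thresholded lists held 2805 peaks in replicate 1 and 3081 in replicate 2. The conservative list of the series held 4594 peaks, which made 4300 separate regions after overlapping peaks were merged, and it covered 1.03% of the genome with a median peak width of 340 bp. The series-level list held 4782 peaks, 3472 of them also in the conservative list. The ranked lists, which also hold unreproducible peaks, ran to 89959 and 98987 peaks for the series and to 54414 and 58006 for replicates 1 and 2.

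The gene that encodes the tagged protein, Phs (FBgn0036522), lies on the plus strand of 3L from 15619901 to 15624130. Of the peaks in the conservative list, 3 lay within 2000 bp of it. One had its summit at 3L:15619794, 107 bp upstream of the gene start, and ranked 852 with a signal of 164. The others had summits at 15625314 and 15625851, inside an intron of another annotated gene, with signals of 489 and 197. All 3 were also found in the thresholded list of each replicate. A transgene adds its own copy of this DNA, so a peak at this locus is uncertain.

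The strongest sites of the conservative list lay mostly at promoters, and both replicates ranked them alike. Peaks that this list leaves out, the strongest with a signal of 1464, are described below and were not ranked here. Of the 25 peaks of highest signal in the list, 19 were at a promoter, 5 in an intron and 1 between genes, and each ranked 29 or better in both replicates. They were picked by a signal made from both replicates, so these ranks are no separate evidence of agreement. The highest lay in an intron of CG11050 (2L:6612709, signal 1992, 1022 bp from the nearest TSS). It was followed by promoter peaks at CG14100 (3L:19590615, signal 1973), Ugalt, which encodes a nucleotide-sugar transporter (X:2703881, signal 1865), and mRpL41, a protein of the mitochondrial ribosome (2R:15217747, signal 1795). The mRpL41 summit is shared with lncRNA:CR44463. Next came Tcs5, CG7601 and Art3, which share their summits with CHMP2B, CIA30 and mRpS10, then ph-p, a Polycomb group gene (X:2137354, signal 1212), lncRNA:CR44619 and CG32772. The peaks ranked 11 to 20 lay nearest to CG5611, PNPase, Trl, CenG1A, px, mRpL23, CG18549, Adf1, HmgZ and CG13390. Of these, CG5611, CenG1A, mRpL23 and CG13390 share their summits with Mtl, mRpS23, CG9004 and CG17294, in that order. Trl encodes the GAGA factor and Adf1 another DNA-binding transcription factor, and both peaks were intronic, 1524 and 787 bp from the nearest TSS. The last 5 lay nearest to asRNA:CR45928, which shares its summit with the translation factor gene eIF6, Elp5, GstE13, Chro, a chromatin protein gene that shares its summit with Ssl1, and CG13323, whose TSS was 11915 bp away. Elp5 shares its summit with CG1275.

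The replicates shared most of their peaks, and nearly all of their strong ones. Of 2800 peaks of replicate 1 on the main arms, 2120 (75.7%, 95% interval 74.1 to 77.3%) overlapped a peak of replicate 2, against 1.32 ± 0.220% (SD, 1000 placements) for random placement. In the other direction it was 2116 of 3080 (68.7%, 67.04 to 70.3%) against 1.20 ± 0.185%. Both permutation tests gave p = 0.001, the smallest they can give. Of the 25% of peaks with the highest signal 99.4% and 99.5% were shared, and of the 25% with the lowest signal 46.6% and 34.8%. Across 4540 conservative peaks with a partner in both ranked lists, the signals of the replicates correlated with Pearson's r = 0.948 and Spearman's rho = 0.729 (permutation p = 1e-05 for both, the smallest possible). These peaks had been kept for their reproducibility between inputs made from both replicates, so the correlation describes the kept peaks and is no separate evidence of agreement. In 4 groups of equal size by the pooled signal, rho was 0.763 in the strongest and −0.256, −0.467 and −0.0256 in the next 3. A split by a signal made from both replicates can itself give negative values, so these do not show where the agreement lies. Of the 4593 conservative peaks, 46.8% overlapped a thresholded peak of both replicates, 26.9% of 1 replicate and 26.3% of neither.

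CG7372-eGFP was found at promoters and seldom in coding sequence or 3′ UTRs outside them. Exons within 500 bp of a TSS count as promoter here. No control library was analysed, so a general gathering of fragments at active promoters cannot be told apart from binding. This limit holds for all promoter and gene results below. Of 4593 summits, 1944 (42.3%, 40.9 to 43.8%) lay at a promoter, against 13.6 ± 0.514% of random positions, a 3.11-fold excess (permutation p = 0.001, the smallest possible, adjusted p = 0.00175). Introns held 39.3%, against 39.5% of random positions (permutation test, adjusted p = 0.929). Coding sequence held 0.718% against 13.7%, 3′ UTRs 0.914% against 4.42%, and intergenic sequence 15.0% against 27.2% (permutation tests, each adjusted p = 0.00175). 5′ UTRs (0.762%, adjusted p = 0.929) and noncoding exons (1.00%, adjusted p = 0.274) did not pass the permutation test. The promoter share was higher among strong peaks, with 57.0% in the strongest 25% and 33.7% in the weakest 25% (odds ratio 2.60, 2.20 to 3.08, two-sided Fisher's exact p = 3.9e-29, 1148 peaks each).

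**Figure D1:**
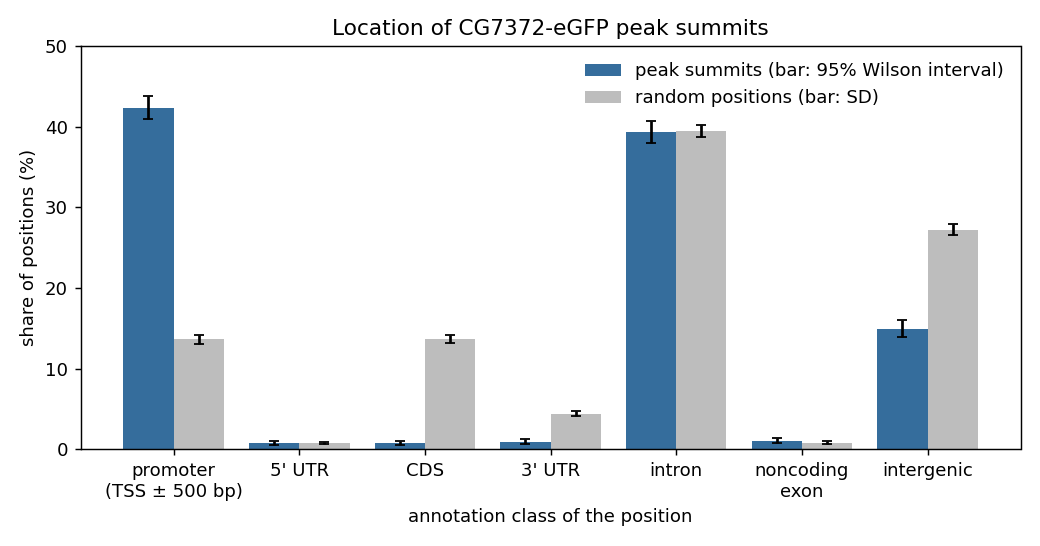
Share of the 4593 conservative peak summits in each annotation class (blue, 95% Wilson interval) beside random positions on the same arms (grey, mean and SD of 1000 placements). Promoters held 42.3% of summits and 13.6% of random positions, while coding sequence outside promoters held 0.718% and 13.7%.

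Peaks were spread over the large chromosome arms and were scarce on chromosome 4 and the Y. The arms 2L, 2R, 3L, 3R and X held 32.6 to 36.8 peaks per Mb. Chromosome 4, a small chromosome with much repeat-rich chromatin, held 6 peaks, 4.51 per Mb, which is 0.133 times the density elsewhere (exact binomial test, adjusted p = 3.35e-12). The Y held 0 peaks (exact test, adjusted p = 6.47e-50), in embryo pools whose sex was not recorded. All ranked peaks, most of them unreproducible, were also scarce there (ratio 0.109 from 96 peaks on 4 and 0.0140 from 32 on the Y), so the scarcity is not particular to the kept peaks. 3L stood slightly above the rest (ratio 1.13, adjusted p = 0.00177), and X did not pass the exact test (ratio 1.07, adjusted p = 0.161). The 3L call was lost without replicate 1 (adjusted p = 0.295) and among the peaks above the median signal (adjusted p = 0.171), and over all alternatives X ranged in this exact test from adjusted p = 0.00101 to 0.395.

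Divergent promoters, where 2 genes start close together and are read in opposite directions, were bound more often than others. A summit lay within 500 bp of the TSS of 1521 of 5052 divergent protein-coding genes (30.1%) and of 809 of 8916 others (9.07%; odds ratio 4.32, 3.93 to 4.74, two-sided Fisher's exact p = 2e-216). One summit can count for both genes of such a pair, so these genes are not independent. Peaks placed at random on the arms bound 4.18 ± 0.309% and 4.15 ± 0.206% of these genes (SD, 100 placements). In all, 2330 of 13968 protein-coding genes (16.7%) were bound.

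Cytosolic ribosomal protein genes, which encode the proteins of the main ribosome, were called bound more often than other genes. Without a control library, this cannot be told apart from fragments gathered at active promoters in general. Of 92 such genes 49 (53.3%) were bound, against 16.4% of the others (odds ratio 5.78, 3.84 to 8.71, Fisher's exact test, adjusted p = 2.59e-14). The members of highest signal were RpS27 (signal 300), RpL32 (287), RpL34b (279) and RpL7 (268). Each shared its summit with a neighbour (Nup37 and sisRNA:CR46364, CG7943, CG8132 and Ripalpha). Of 73 mitochondrial ribosomal protein genes, 28 (38.4%) were bound (odds ratio 3.15, 1.97 to 5.05, Fisher's exact test, adjusted p = 3.62e-05), led by mRpL41, mRpS10, mRpS23 and mRpL23. These leading members share their summits with lncRNA:CR44463, Art3, CenG1A and CG9004, in that order. Among the 73 genes 79.5% were divergent, and against other genes of the same promoter arrangement, an alternative chosen after seeing the data, the odds ratio was 1.88 with an adjusted p of 0.0784 by an exact conditional test. Given only to the nearest TSS, the adjusted p of this list by Fisher's exact test was 0.0631, in a range of 3.42e-05 to 0.0784 over all alternatives. Other broadly active groups did not pass the test. By Fisher's exact test, of 44 translation initiation factor genes 10 were bound (eIF6, eIF3c, eIF5B, eIF1; adjusted p = 0.617), of 84 oxidative phosphorylation genes 17 (ND-ASHI, ND-MWFE, ND-51, COX5A; adjusted p = 0.706), of 48 proteasome genes 8 (Rpn13, Rpn3, Rpn6, Rpn5; adjusted p = 1) and of 26 cell cycle and DNA replication genes 4 (Dp, Mcm2, Cdk1, dup; adjusted p = 1).

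Genes for insulator and architectural proteins, which organise chromosome domains, were also bound more often, at 7 of 14 (50%, odds ratio 5.01, 1.82 to 13.8, Fisher's exact test, adjusted p = 0.0144). The bound members were Chro (signal 888), Cp190 (455), row (258), pzg (153), M1BP (149), BEAF-32 (118) and pita (73.8). The others, CTCF, Ibf1, Ibf2, ZIPIC, dwg, mod(mdg4) and su(Hw), had no summit within 500 bp of a TSS. Of the 7 bound members, row and pita were the ones that did not share the summit with another gene. This call rests on few genes, and its adjusted p was 0.0642 without replicate 2, 0.0611 with the series-level list, 0.111 against genes with a ranked peak and 0.196 with the nearest TSS, in a range of 0.00376 to 0.196 over all alternatives. Of 20 Polycomb and trithorax group genes, which maintain gene silencing and activity, 7 were bound, led by ph-p (signal 1212), brm (823), E(z) (363) and Trl (219). The brm and E(z) summits are shared with Arl1 and Cnep1r2. The ph-p summit lies 499 bp from the TSS, outside the 200 bp setting given next. The list did not pass Fisher's exact test (odds ratio 2.78, 1.14 to 6.79, adjusted p = 0.177), and at a TSS distance of 200 bp it did (adjusted p = 0.0169, in a range to 0.538 over all alternatives).

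**Figure D2:**
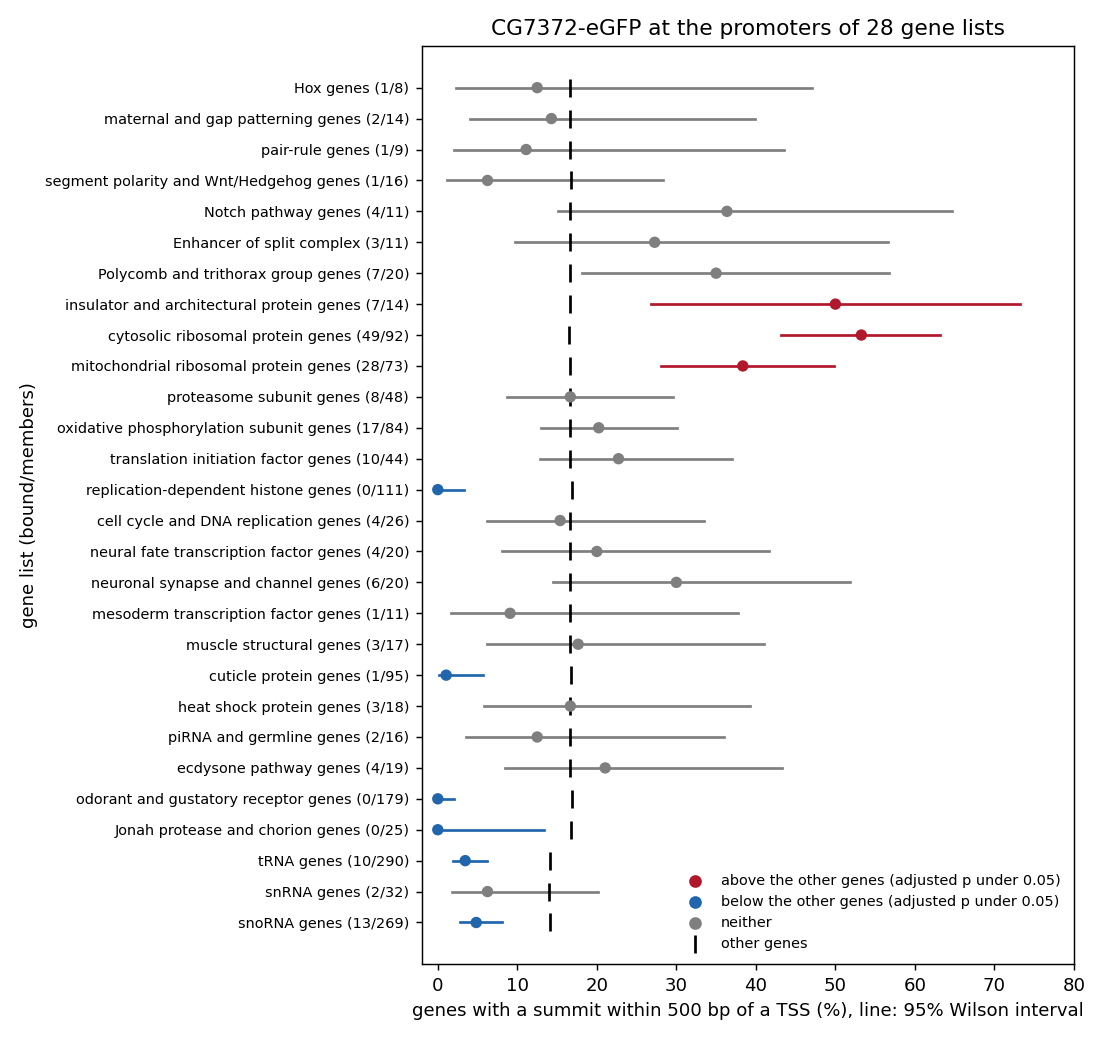
Share of genes with a summit within 500 bp of a TSS in each of 28 gene lists (points, 95% Wilson interval), beside the share of the other genes (black ticks). The lists above the other genes are the cytosolic (53.3%) and mitochondrial (38.4%) ribosomal protein genes and the insulator and architectural protein genes (50%).

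No list of embryonic patterning genes passed the test against other genes, though individual members were bound. Of 8 Hox genes, which set segment identity, pb was bound (signal 193), while Abd-B, Antp, Dfd, Scr, Ubx, abd-A and lab were not. Of 9 pair-rule genes hry was bound (signal 293, summit at −170 bp from the TSS), while eve, ftz, odd, opa, prd, run, slp1 and slp2 were not. Of 14 maternal and gap genes 2 were bound, bcd, the anterior determinant (signal 133), and nanos, the posterior determinant (74.4, shared with CG11779). Of 16 segment polarity genes 1 was bound, nkd (187). Each of these 4 lists had an adjusted p of 0.820 or more by Fisher's exact test. By Fisher's exact test, of 11 Notch pathway genes 4 were bound (mam, neur, Su(H), mib1; adjusted p = 0.244), and of the 11 genes of the Enhancer of split complex, which act downstream of Notch, 3 were (E(spl)m3-HLH, E(spl)m2-BFM and E(spl)m7-HLH; adjusted p = 0.714). With 8 to 16 members a list can hide a moderate difference, as the intervals of 2.24 to 47.1% for the Hox genes and 1.11 to 28.3% for the segment polarity genes show.

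Groups of the nervous system, muscle and hormone response did not pass the test. In exact tests, of 20 neural fate genes 4 were bound (nub, pros, pdm2, da; adjusted p = 1), and of 20 synapse and channel genes 6, led by elav, the neuronal RNA-binding protein (signal 518), Sh, cpx and comt (adjusted p = 0.299). Of 11 mesoderm transcription factor genes 1 was bound, tin, which is needed for heart formation (signal 324; exact test, adjusted p = 1). Of 17 muscle structural genes 3 were bound (wupA, sls, Tm1; exact test, adjusted p = 1), of 19 ecdysone pathway genes 4 (Eip74EF, Eip75B, usp, ftz-f1; adjusted p = 0.845), of 18 heat shock protein genes 3 (Hsp27, Hsp83, Hsp26; adjusted p = 1), of 16 piRNA and germline genes 2 (cuff, spn-E; adjusted p = 1) and of 32 snRNA genes 2 (snRNA:U1:95Ca, snRNA:U5:35D, the latter with a signal of 9.86; adjusted p = 0.617). All of these are Fisher's exact tests adjusted over the 28 lists.

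Several gene families were bound less often than other genes, though not all less often than random placement gives. None of 179 odorant and gustatory receptor genes was bound (interval 0 to 2.10%, Fisher's exact test, adjusted p = 1.21e-13), and 1 of 95 cuticle protein genes was (Cpr47Ea, signal 144; adjusted p = 6.24e-06). None of 25 Jonah protease and chorion genes was bound (0 to 13.3%; exact test, adjusted p = 0.0471), a call that was lost in 8 of 10 alternatives. None of 111 replication-dependent histone genes was bound (exact test, adjusted p = 2.32e-08), but 2 of them had any ranked peak, and these repeated genes are uncertain. Of 290 tRNA genes 10 were bound (among them tRNA:Leu-CAG-1-3, tRNA:Leu-CAG-1-4, tRNA:Tyr-GTA-1-8 and tRNA:Phe-GAA-1-2; exact test, adjusted p = 2.32e-08), also uncertain as a family. Of 269 snoRNA genes 13 were bound (snoRNA:Or-aca5, snoRNA:Psi28S-2949, snoRNA:Psi18S-1275 and snoRNA:Or-CD11a lead; exact test, adjusted p = 8.88e-06), and at a TSS distance of 1000 bp the snoRNA odds ratio was 1.03. Peaks placed at random bound 3.41 ± 1.43% of tRNA genes and 3.46 ± 1.75% of snoRNA genes (SD, 100 placements), where 3.45% and 4.83% were found. For the receptor genes random placement gave 3.74 ± 1.46%, for the cuticle genes 3.62 ± 1.89%, for the histone genes 3.46 ± 2.19% and for the Jonah and chorion genes 3.80 ± 3.99%. The receptor genes alone of these 6 lists lay more than 2 SD below random placement, so the other 5 calls do not show avoidance.

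A family of short sequences was centred in the peaks. Of 32896 possible 8-bp words, 308 were more frequent at summits than in flanks on 2L, 3L and 4, and 273 of these also passed on 2R, 3R and X. The first was CATACGCC, present at 9.56% of summits and 0.137% of flanks on the first arms and at 8.65% and 0.308% on the others (2763 summits, one-sided Fisher's exact test, adjusted p = 2.77e-92). The words GCGTATAC and CGCATACG followed, and all 10 leading words hold the bases CGTAT on one strand. At least 1 of these 10 occurred at 21.2% of the 2763 summits on 2R, 3R and X (19.7 to 22.7%) and at 1.45% of their flanks, at a median distance of 13.5 bp from the summit. Of the 308 words, 35 held the bases CGTAT on either strand and 78 were made of A and T alone. Any of the 308 occurred at 89.0% of summits over all arms and at 60.7% of their flanks. Summits were richer in A and T than flanks, and these word tests did not adjust for that. A weight matrix fitted after seeing the data had the consensus ACGYATACGCCNYG and placed a site at 25.1% of those summits and 5.65% of flanks. Its area under the curve over the 2763 summits on 2R, 3R and X was 0.535, so most of them were not separated from their flanks by this sequence. There it was 0.447 in the strongest 25% of peaks and 0.589 in the weakest 25%. In the strongest 25% a site was placed at 19.3% of summits and 6.10% of flanks, in the weakest at 25.4% and 5.38%. The low area in the strongest 25% thus does not show that the sequence was absent there, and base composition was not adjusted for.

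**Figure D3:**
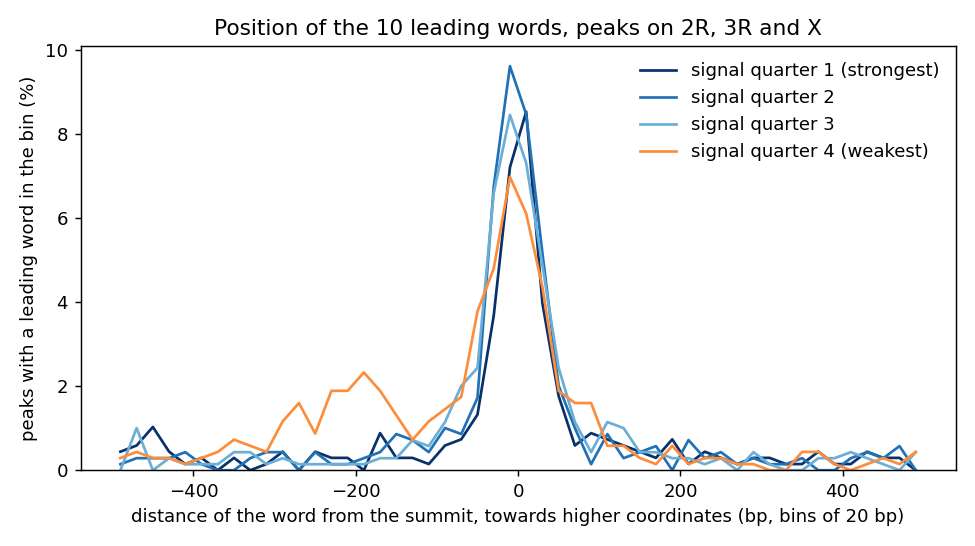
Share of peaks on 2R, 3R and X with a leading word in each 20 bp bin, by distance from the summit in bp, for 4 groups of equal size by signal. In every group the words peak at the summit, and the weakest has a second rise near 200 bp towards lower coordinates. Over all arms, 284 peaks of the weakest group are the weaker of an overlapping pair. In 290 of 292 pairs the stronger summit lies at the lower coordinate, at a median distance of 203 bp over all pairs. The rise is thus no evidence of a second site of the weak peaks themselves.

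The leading words were less frequent at promoters, and over all peaks at the strongest. They occurred at 8.67% of promoter summits (7.20 to 10.4%) on 2R, 3R and X, with an odds ratio against other summits of 0.218 (0.173 to 0.274, Fisher's exact p = 4.25e-47). In 4 groups of equal size by signal, over all arms, they occurred at 15.1%, 23.3%, 26.1% and 22.7% of summits, from the strongest to the weakest. Strong peaks are more often at promoters, and within promoter peaks on 2R, 3R and X the odds ratio, strongest against weakest 25%, was 1.20 (0.665 to 2.16). Of the 1148 weakest peaks, 284 were the weaker of an overlapping pair, described below. All 292 such peaks held a leading word in 4.11% and lay at promoters in 42.5%. In the rest of the weakest 25% it was 28.9% and 31.1%. Such peaks may thus lower the word shares of the weakest 25%, within promoters as well. Outside promoters the shares over all arms were 24.8% (21.2 to 28.8%) and 29.8% (26.7 to 33.2%). Of the 25 strongest peaks 0 held a leading word, which allows a share of up to 12% at 3 counts (Wilson interval 0 to 13.3%). Summits of the strongest 25% were rich in A and T, at 67.02% against 55.8% in flanks, a difference of 11.2 percentage points (10.4 to 11.99), while in the weakest 25% it was 0.981 points (0.193 to 1.77). Base composition was compared after the words had been seen.

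**Figure D4:**
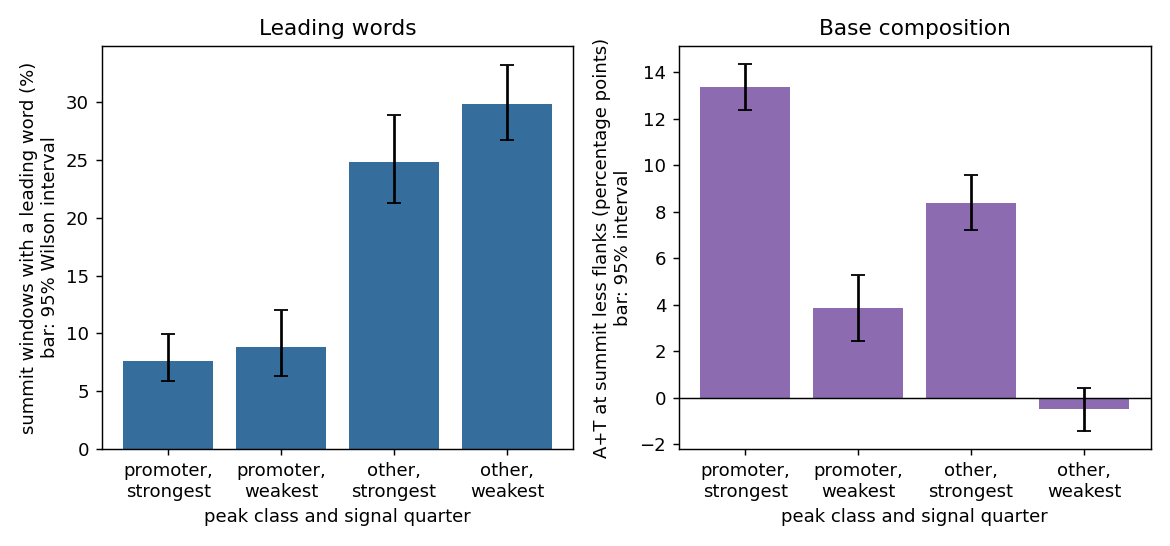
Share of summit windows with a leading word (left, 95% Wilson interval) and A+T content of summits less flanks in percentage points (right, 95% interval), for promoter and other peaks in the strongest and weakest 25% by signal. Promoter peaks of the strongest 25% hold the words at 7.65% and have 13.4 points more A+T than their flanks.

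Several known promoter and insulator sequences differed between summits and flanks. Summits were also richer in A and T (62.4% against 57.0% over all peaks), and these tests did not adjust for base composition. An excess of A+T-rich sequences such as TATAAA at summits cannot be told apart from this difference. The same holds for a deficit of sequences with more G and C, such as the GAGA factor sequence and the E-box. The TATA box sequence TATAAA occurred at 17.0% of summits and 11.1% of flanks (odds ratio 1.64, two-sided Fisher's exact test over 10 sequences, adjusted p = 1.32e-20). The DREF sequence, bound by a factor of replication and housekeeping genes, occurred at 1.20% and 0.348% (odds ratio 3.44, exact test, adjusted p = 4.83e-08), the BEAF-32 core at 13.7% and 10.9% (adjusted p = 4.94e-06) and the su(Hw) core at 2.39% and 1.30% (adjusted p = 7.43e-06). The DREF sequence contains the BEAF-32 core, so these results overlap. Its 55 summits and 32 flanks are among the 631 and 1003 with that core. The GAGA factor sequence was rarer at summits, at 0.958% against 2.75% (odds ratio 0.345, exact test, adjusted p = 1.86e-12), as was the E-box CAGCTG at 3.74% against 5.15% (adjusted p = 0.000325). The M1BP (adjusted p = 0.186), zelda (0.172), CTCF (0.926) and pho (0.186) sequences did not pass the exact test. With windows holding a leading word left out, an alternative chosen after seeing the data, pho was called rarer at summits (14.7% against 18.5%, odds ratio 0.756, exact test, adjusted p = 3.46e-07, in a range to 0.904 over all alternatives). The pho core GCCAT can overlap the end of the leading words, so leaving out their windows also removes pho sites at summits, and this call does not show that pho sites are avoided. The DREF call was lost without replicate 2 (odds ratio 1.26, exact test, adjusted p = 0.594, in a range from 1.34e-10 to 0.594). With windows holding a leading word left out, the su(Hw) core (odds ratio 1.78), the GAGA factor sequence (0.335) and the E-box (0.639) kept their calls. With windows holding any called word left out, which kept 503 summits, they were not called (1.07, 0.529 and 1.23), but one called word contains the su(Hw) core, so that value does not test it. Soft-masked repeats made up 23.3% of the bases at summits and 20.1 ± 0.393% at random positions (permutation p = 0.001, the smallest possible).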

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

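The tests of word density in promoter sequence, of word shares within the weakest 25% of peaks, and both tests of overlapping pairs were chosen only after the results they bear on had been seen; the tests of the left-out peaks and of whole promoter peaks were set before their values were computed, on data that had been looked at.

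A signal lay in data outside the main peak list. The ranked conservative list holds 79 peaks on the main arms with an IDR of 0.01 or less that the thresholded list leaves out, and the strongest has a signal of 1464 (2L:480932-481257), rank 5 of all ranked peaks, in the gene ush. Others lie in Lk6, larp and trx, named here after their values were seen. Of the 79, 51 lie on 3R and 21 on 2L. Misplaced reads at repeats as the whole cause are argued against by the 7.59% of these summits with a leading word (3.53 to 15.6%), above the 1.37% of flanks of the kept peaks, and 19.5% of their bases are soft-masked. That they are simply a random part of the kept kind is argued against by the odds ratio of 0.242 (0.101 to 0.582) for a leading word against kept peaks nearest in signal. Removal of the whole stretches between neighbouring left-out peaks is argued against by 3 kept peaks inside them, where 7.46 would lie at the genome's density. The left-out peaks are clustered, with 59 of the 79 in 19 stretches and up to 10 in one, and the shortfall of kept peaks there has a one-sided p of 0.0607 by an exact Poisson test, so regional exclusion in part stays open. Shorter excluded segments were not tested and may still account for the peaks, since the 3 kept peaks speak only about whole stretches. No biological explanation was tested, because the design has 1 group.

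The leading words were less frequent at promoter peaks than at other peaks. A summit that lies away from the word is argued against by the whole peaks, where the odds ratio is 0.214 (0.174 to 0.263). Scarcity of the words in promoter sequence as the whole cause is argued against by the density of their sites there, which is 0.868 times that elsewhere (0.820 to 0.918). The greater strength of promoter peaks is argued against by the weakest 25% of peaks alone, with an odds ratio of 0.207 (0.124 to 0.347). What stays open is that many promoter peaks may form without direct contact with these words, or that the antibody or open chromatin gathers fragments at active promoters, which needs a control library that was not analysed here.

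The weaker peak of an overlapping pair lay at the higher coordinate in 290 of 292 pairs of the conservative list, at a median distance of 203 bp, and on that side in 82.1 to 99.3% of pairs in the 8 lists. Separate neighbouring binding sites as the whole cause are argued against by this one-sidedness, since real neighbours have no preferred side of the map. Of the 238 kept peaks with a signal under 20, 97.9% are the weaker of a pair (95.2 to 99.1%), and under a limit of 10 it is 167 of 169; both limits were chosen after seeing the data. A candidate explanation is thus a second peak that passes on the reproducibility of a stronger neighbour, and these peaks make up 24.7% of the weakest 25% of peaks and hold a leading word in 4.11% against 28.9% in the rest of it. Rab3 (signal 4.25) and snRNA:U5:35D (signal 9.86) are called bound through peaks of such low signal.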

How the results depend on the processing

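The alternatives with unreproducible peaks, ranked-peak genes or genes of the same arrangement as background, the weight matrix, and windows without a called or leading word were chosen after seeing the data; the others were planned. Of 473 recomputed values, 388 kept their direction and their side of the threshold, among them 91 of 99 for the main results; 20 single calls were lost and 4 were gained without a turn of direction, and among the values that turned 2 more were lost and 1 was gained. The promoter excess, the higher promoter share of strong peaks, the divergent promoters, the low density on chromosome 4, the repeat share, the sharing of peaks and the rank correlation kept theirs in every alternative run on them. Against unreproducible peaks (IDR above 0.5) the promoter odds ratio was 3.99. The cause of each change below was not tested unless stated. A stricter IDR score removed no peak, so that setting shows nothing. No paired analysis was possible because there is 1 group. Depth is unknown, and 2 replicates limit every statement.

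Without replicate 1 or 2, the called words numbered 205 to 276 and those past the second set of arms 175 to 234, from shorter lists with 159 and 182 words in common with the main one. The X ratio was then 1.10 to 1.15 and passed the test without replicate 2; among peaks above the median signal it was 1.21 and also passed. With each peak given to the nearest TSS 1 list stood above the other genes, the cytosolic ribosomal proteins. The lists below the others fell to 3 with the same arrangement and to 2 with ranked-peak genes, where the 2 RNA classes were left out by construction. With windows holding a called word left out, 0 known sequences were below flanks, from 503 summits.

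Direction turned in 55 values of 16 results. Of these, 2 had been called: the snoRNA odds ratio was 1.03 at 1000 bp, and the E-box 1.23 without called words. The other 53 were not called in the main result, and 1 was called in the alternative: CTCF without replicate 2 (exact test, adjusted p = 0.0148). They are odds ratios or ratios that cross 1. Without a replicate they ranged for Hox from 1.33 to 1.49, maternal and gap 0.828 to 2.03, pair-rule 1.18 to 1.32, Notch 0.324 to 1.76, proteasome 0.39998 to 0.843, cell cycle 1.11 to 1.33, synapse 0.512 to 0.573, mesoderm 0.952 to 1.96, piRNA 0.721 to 1.15, CTCF 0.501 to 0.971 and 3R 0.973 to 1.01. With the series-level list proteasome was 0.896 and mesoderm 1.30. Above the median signal Hox was 1.64, pair-rule 1.45, Notch 0.356, proteasome 0.439, cell cycle 1.22, synapse 0.630, mesoderm 1.17, 3R 0.954, M1BP 0.856 and CTCF 0.761. With merged peaks Hox, maternal and gap and cell cycle were each 1.004 and CTCF 0.970. At 200 bp pair-rule was 1.35, cell cycle 1.53 and muscle 0.694. At 1000 bp proteasome was 0.852, cell cycle 1.29, muscle 0.981 and piRNA 1.05. With the nearest TSS Hox was 1.49997, pair-rule 1.32, cell cycle 1.12 and mesoderm 1.07. With flanks at 200 bp M1BP was 0.780 and CTCF 0.994. Without called words, some of which contain the pho core, pho was 1.04, and without leading words CTCF was 0.947. With the same arrangement Hox was 1.43, maternal and gap 1.24, pair-rule 1.25 and proteasome 0.760, and with ranked-peak genes pair-rule was 1.31.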

Other observations

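The comparison of word sites by promoter class, the search for further sequences and the unreproducible peaks were chosen only after other results had been seen; the tests on chromosome 4 and on weaker peaks were written before their values were computed, but on data that had been looked at, and they were left out for a time after their values had been seen.

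Few sites of the leading words lay at the summit of a kept peak. Occupancy itself was not measured, and sites outside the summit windows of kept peaks may still be bound. On 2R, 3R and X, a summit window of a kept peak covered 8.35% of 1366 sites of these words in promoters (6.99 to 9.93%) and 5.54% of 10080 sites elsewhere (5.11 to 5.999%). Summit windows are denser in promoters and cover 1.09% of all bases there and 0.229% elsewhere, so the sites were at summits 7.66 and 24.2 times as often as bases in general. Among 68241 ranked peaks with an IDR above 0.5, 15.5% of summits lay at promoters and 2.09% held a leading word.

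The scarcity of peaks on chromosome 4 was set against its sequence. Fewer bases outside repeats as the whole cause is argued against by the peaks per Mb of unmasked sequence, 0.145 times those of 2L, 2R, 3L, 3R and X (0.0531 to 0.315). Fewer copies of the leading words as the whole cause is argued against by the peaks per copy, 0.255 times those on the same 5 arms (0.0937 to 0.556), from 6 peaks. All peaks are counted there, while 21.8% of summits over all arms hold a leading word. Whether fewer copies lower the number of peaks with such a word was not tested. Among all ranked peaks, most of them unreproducible, the density on this chromosome was 0.109 times that elsewhere, the Y included (96 peaks), so the scarcity is not particular to the kept peaks. Other features of this chromosome, such as its chromatin, stay untested.

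An expectation that leading words would be less frequent at weaker peaks was written before the values were computed, and it failed. On 2R, 3R and X the odds ratio of a leading word, strongest against weakest 25%, was 0.714 (0.544 to 0.937), so the words were less frequent at the strongest peaks. The tests of its 2 proposed causes therefore decide nothing. The difference over whole peaks less flanks was −7.46 percentage points (−12.3 to −2.63), and within promoter peaks the odds ratio was 1.20 (0.665 to 2.16).

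A further sequence was sought in the 976 of 1148 peaks of the strongest 25% without a leading word. Of 300 weight matrices, the 10 that best separated summits from shuffled sequence on 2L, 3L and 4 gave an area under the curve of 0.592 to 0.641 against shuffled sequence on 2R, 3R and X. Against flanks there it was 0.303 to 0.492 for these 10 and 0.206 to 0.7501 for all 300, with 49 above 0.5. The highest, also the best against flanks on the fitted arms, was 83.3% A and T, and A and T content alone gave 0.847, so no matrix separated summits from flanks better than base composition did. The method missed a planted word at 4.65% of windows in simulated data, so a sequence at few sites was not excluded.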
